A study of Mus musculus with 64 samples.

How the data were processed

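Two-channel arrays measured tissue captured by laser microdissection from mice carrying 4T1-2776 or 4T1-2792 cells. Per the labels, 5 ng of RNA was amplified, 5 ug of product was labelled with Cy3, and universal mouse reference RNA was labelled with Cy5. The deposited table of the series holds log2 values per gene symbol for 64 samples, made by the authors with Agilent Feature Extraction 9.5.3.1 and limma per the submitters' processing notes. Per the file headers, the scanner files of 32 arrays, all of 4T1-2792, came from Feature Extraction 10.7.3.1 and hold spot and background intensity in both channels, processed intensity, and other values, which are flags for spots well above background, saturated or uneven. Scanner files of 4T1-2776 were not used here.

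Groups were taken from the labels. Of 64 samples 63 were placed in 22 groups, and 1 sample with conflicting labels was left out. The label number together with line and time names an animal, and samples of the same number were taken to be of the same animal. Of the residuals of samples that share an animal, 28 pairs in 4T1-2776 had a median correlation of -0.214, with 12 above 0.1, and 30 pairs in 4T1-2792 of 0.1, with 15 above 0.1, where other pairs of 4T1-2792 had -0.00499. The pairing rests on the labels. No 2 samples held identical values. The p-values measure the spread between these samples.

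The design, fixed before the data were examined, called for the deposited table in 1 fit over both lines if its 4T1-2792 columns correlated at 0.8 or more with log2 ratios from the scanner files. The median correlation over arrays was 0.197 with the log2 ratio and 0.946 with the log2 Cy3 signal. The deposited values were therefore read as log2 Cy3 intensity, which was checked for 4T1-2792 columns and is assumed for 4T1-2776. As the design set out for this case, 4T1-2792 was analysed from the scanner files, 4T1-2776 from the deposited table as scaled by the authors, each line in its own fit, and the 6 contrasts between the lines were not run.

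For 4T1-2792, background was corrected by normexp with an offset of 50, ratios of Cy3 to Cy5 were normalised by loess within each array, control spots were left out, and the probe with the highest mean Cy3 signal stood for each of 20660 gene symbols. The 28446 probes without a gene symbol were left out. Spots did not saturate, and 24.7% to 44.6% of probes per array stood well above background in Cy3. The 4T1-2776 table gave 15396 genes, after 24 date-like names of the series table were left out. Of the names, 10378 of 4T1-2776 and 14459 of 4T1-2792 were current symbols of the reference annotation GRCm38.p6, which served for names only, and 674 and 954 more were renamed from synonyms. Coordinates are not given, since the array annotation follows another build. Among 4T1-2792 genes of the naming rule with several probes, a probe moved the opposite way for 0 of 26 in metastasis minus primary tumour, 2 of 7 in metastasis margin minus core, 0 of 5 in primary tumour margin minus core, 1 of 6 in adjacent minus distant liver, 3 of 13 in 3 weeks minus 10 days and 2 of 24 in core minus distant liver.

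Each line was fitted with limma 3.58.1 in R 4.3.3 (with version 1.5.0 of statmod and 1.17.8 of data.table) by a model of group means with animal as a random block, whose correlation was -0.0591 in 4T1-2776 and 0.0122 in 4T1-2792. The 6 contrasts per line averaged the groups of each tissue, with 10 days left out of metastasis minus primary tumour because it had no margin. Tests were two-sided and moderated by eBayes, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. For 33 gene lists fixed before the data were examined, members past the threshold were counted over all genes and adjusted over the list alone. Lists with at least 3 measured genes were tested with camera on data whitened by the block correlation, with a preset correlation of 0.01 and beside it an estimated one, adjusted over the lists within a contrast. Some genes stand in more than 1 list, such as Lcn2 in the neutrophil and acute-phase lists and Fga and Fgb in the hepatocyte and acute-phase lists. Many markers are also expressed by more than 1 of the tissues compared.

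Genes named in the text were chosen by a rule fixed before the data were examined. In each contrast, among genes past the threshold with a proper symbol, it took the 8 highest and 8 lowest log2 changes. In metastasis minus primary tumour it added the 8 highest among genes higher in cores than in distant liver, and in adjacent minus distant liver the 8 highest among genes lower in cores. For each list spoken of it took up to 4 members past the threshold or otherwise 2 as values, and it allowed a fixed set of check genes. The text leaves out some genes of the rule. In 4T1-2792 a gene that stood above background on no array of 1 side has its fold given as a lower bound of the Cy3 signal, beside the fold of the ratios. Group means and SD are over animals, with the samples of an animal on 1 side averaged first.

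The fit was tested on simulated data with 100 genes changed by 1 log2 and 100 by 2 log2, with the spread and group sizes of each contrast. In metastasis minus primary tumour it recovered 85% and 98% of them among 15396 genes in 4T1-2776 and 84% and 100% among 20523 genes in 4T1-2792. In primary tumour margin minus core it recovered 71% and 93% in 4T1-2776 and 57% and 96% in 4T1-2792. False calls made up 2.38% to 7.19% of calls over all contrasts. The simulated noise was independent between genes and arrays and held no slide, array or animal effect. These shares therefore need not hold for the measured data. The number of arrays limits the precision.

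Alternatives were no animal block, quantile or median scaling, array weights, robust eBayes, a 2-fold minimum, single time points or tissue parts, a hepatocyte covariate, the mean of probes, a filter on dim probes, Feature Extraction signals, Cy3 alone, slide as a block and each animal left out. Chosen after seeing the data were slide as a random block, slide 3 alone, the deposited table for 4T1-2792, the fit without 1 doubtful array, the share of genes below log2 10 as a covariate and differences between time points, with and without slide as a block. The genes of 4T1-2792 metastasis minus primary tumour were compared with slide 3 on shared primary tumour arrays, so 20 simulations of noise without any change took as many genes, and the primary tumour animals were split. Other splits of the samples were counted, at most 100 per comparison. Results of some single genes are not reported here.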

Results

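Gene expression was measured with 2-colour Agilent mouse arrays in tissue captured by laser microdissection from female Balb/c mice carrying 4T1-2776 or 4T1-2792 cells, sub-populations of the mouse mammary carcinoma line 4T1 that spread to the liver. Cells were placed in the mammary fat pad to grow primary tumours, or in the spleen to seed the liver. Of 64 samples, 63 fell into 22 groups, 11 per line. The groups of each line were primary tumour core and margin, metastasis core at 10 days, 2 weeks and 3 weeks, metastasis margin at 2 and 3 weeks, and liver adjacent to and distant from metastases at 10 days and 2 weeks. Each group held 3 samples from 3 animals, except 4T1-2776 adjacent liver and metastasis core at 2 weeks and 4T1-2792 distant liver at 2 weeks, which held 2. The 4T1-2776 samples covered 31 arrays of 12 animals and the 4T1-2792 samples 32 arrays of 12 animals. Values were log2 Cy3 intensities for 4T1-2776 (15396 genes) and log2 ratios of sample to a universal mouse reference for 4T1-2792 (20660 genes). The lines were fitted apart, so no difference between them was tested.

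The first comparison asked how metastases in the liver differed from primary tumours in the mammary fat pad. In 4T1-2776, transcripts made by hepatocytes set the metastases apart. Albumin (Alb) measured 14.14 ± 0.49 log2 units (SD, n = 6 animals) in metastases and 8.84 ± 0.11 (n = 3) in primary tumours. Haemopexin (Hpx), which binds haem in plasma, measured 15.88 ± 0.33 against 9.01 ± 0.24. Of 20 measured genes of the hepatocyte list 15 rose and none fell (18 rose when adjusted over the list alone), and of 20 acute-phase genes 11 rose (16 over the list alone). The fibrinogen chains Fgb and Fgg rose by 6.22 and 6.54 log2, and haptoglobin (Hp) by 4.23, and the protease inhibitor Serpina1c measured 16.11 ± 0.39 against 9.16 ± 0.15, with every metastasis animal above every primary tumour animal. The scavenger receptor Stab2 of liver sinusoidal endothelium rose by 2.13 log2 (adjusted p = 9.05e-07), without overlap between animals.

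Genes of hypoxia and glycolysis also rose in 4T1-2776 metastases, 5 of 18 with none falling. Among them were Car9, a carbonic anhydrase induced by low oxygen (log2 change 1.19 ± 0.30 SE, adjusted p = 0.0465), Ndrg1 (1.08 ± 0.23, adjusted p = 0.00848), Bnip3 (0.98 ± 0.21, adjusted p = 0.00774) and Higd1a (0.87 ± 0.13, adjusted p = 9.68e-05). Animals of both tissues overlapped for Car9 and did not for the other 3. Of 16 neutrophil genes, S100a9 (3.83 ± 0.60, adjusted p = 0.000271) and Lcn2 (2.57 ± 0.49, adjusted p = 0.00328) rose, and 6 rose over the list alone. The partner of S100a9 in calprotectin, S100a8, measured 12.96 ± 1.32 against 10.51 ± 0.14 (adjusted p = 0.0738). The stromal genes Dcn, Sparcl1 and Tagln rose by 1.48, 1.58 and 1.24 log2. Lower in metastases were the monocyte-attracting chemokine Ccl8 (11.06 ± 1.07 against 13.70 ± 0.34, adjusted p = 0.00016), its relative Ccl12 (-1.50 ± 0.29, adjusted p = 0.00315) and Cfd, the complement factor D made in fat (-2.05 ± 0.14, adjusted p = 3.23e-10), each without overlap between animals. Cfd measured 14.81 ± 0.43 at the margin of primary tumours and 11.42 ± 0.45 in their core (SD, n = 3 each). The comparison averages both parts, so much of its fall rests on the margins. The interferon-induced genes Oas1a and Ifi44 fell by 0.67 and 0.85 log2. They were 2 of 14 type I interferon genes to pass (6 over the list alone), and the median of that list was -0.62. Keratins of the tumour epithelium and vimentin differed little. Krt18 measured 17.34 ± 0.14 against 17.43 ± 0.06, Krt8 12.68 ± 0.15 against 12.81 ± 0.18 and Vim 15.61 ± 0.22 against 15.81 ± 0.02 (each adjusted p = 1).

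In 4T1-2776 limma found 251 of 15396 genes past an adjusted p of 0.05, 220 higher and 31 lower in metastases. Array weights gave 1427 (830 higher, 597 lower), and the share of dim genes on each array as a covariate gave 743 (338 higher, 405 lower), so that balance depended on the setting. In limma's camera test the hepatocyte (median log2 1.84, adjusted p = 5.71e-106), acute-phase (0.98, adjusted p = 1.84e-58), hypoxia (0.22, adjusted p = 1.33e-09) and neutrophil lists (0.47, adjusted p = 2.89e-10) passed, and they also did with an estimated correlation (adjusted p = 4.85e-07, 1.31e-05, 0.0121 and 0.0464). The type I interferon list passed with the preset correlation only (adjusted p = 3.41e-09, and adjusted p = 0.0793 with an estimated correlation). With the hepatocyte level of each sample as a covariate the count was 16 genes and Stab2, Bnip3 and Dcn turned to -0.84, -0.50 and -0.97. With metastasis cores set against primary tumour cores the count was 123, and Car9 and Bnip3 stood at -0.11 and -0.25. That setting leaves out the margins of both tissues. Car9 measured 14.08 ± 1.03 in primary tumour cores and 12.30 ± 0.30 in their margins (SD, n = 3 each, limma adjusted p = 0.354).

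In 4T1-2792 metastases, 17 of 20 hepatocyte genes and 17 of 24 acute-phase genes rose and none fell (over the list alone, 18 rose and 1 fell, and 18 rose). Hpx measured 6.40 ± 0.99 log2 units relative to the reference (SD, n = 6 animals) in metastases and 0.06 ± 0.21 (n = 3) in primary tumours, Hp 4.88 ± 0.55 against -0.67 ± 1.26 and Apoc1, a lipoprotein component, 4.31 ± 0.63 against -0.91 ± 0.25, without overlap between animals. In the Cy3 channel alone, Alb was at least 59.5-fold higher (26.6-fold by ratios, adjusted p = 1.55e-10), the plasma carrier Ahsg at least 308-fold (79.5-fold by ratios, adjusted p = 2.98e-12) and Fgg at least 148-fold (65.4-fold by ratios, adjusted p = 1.22e-11). Genes given as at least stood above background on no array of the lower tissue, where their Cy3 level was set to the larger of its signal and the array's detection level. Those folds bound the Cy3 signal and not the ratio to the reference, and dyes were not swapped. Hypoxia and glycolysis genes rose here too, 13 of 20 with none falling. Adm, a vasodilator peptide induced by low oxygen, measured -1.32 ± 0.28 against -3.31 ± 0.36, and Bnip3 rose by 1.44 ± 0.23 log2 (SE, adjusted p = 7.02e-05). Neutrophil genes rose in 11 of 17 and fell in 2 (13 and 4 over the list alone). Values given on slide 3 compare the primary tumours with metastasis cores of 10 days, a time outside the main comparison. S100a8 measured 3.29 ± 1.20 against -0.08 ± 0.63, Lcn2 2.94 ± 0.61 against -0.84 ± 0.44, the granule peroxidase Mpo rose by 3.49 ± 0.56 (adjusted p = 8.77e-05, and 2.62 with adjusted p = 0.25 on slide 3), the granule peptide Camp was at least 32-fold higher in Cy3 (16.2-fold by ratios, adjusted p = 1.81e-07, but a log2 ratio of 1.21 with adjusted p = 0.952 with slide as a block), and the cytokine Il1b fell by 2.17 (adjusted p = 4.81e-06), though it stood at -0.20 with slide as a block (adjusted p = 0.992) and at 1.05 on slide 3 (adjusted p = 0.155). Of 18 cholesterol synthesis genes 8 rose, such as Fdps by 0.69, and 10 rose over the list alone.

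Interferon-response genes and some genes of other immune and stromal cells were lower in 4T1-2792 metastases than in primary tumours. Of 18 type I interferon genes 15 fell and none rose, and of 17 genes of interferon gamma response and antigen presentation 12 fell (15 over the list alone). The ubiquitin-like Isg15 measured 0.23 ± 0.94 against 1.65 ± 0.63 (-0.33 with slide as a block, adjusted p = 0.983, and -0.67 on slide 3, adjusted p = 0.721), Oas1a 1.11 ± 0.80 against 2.55 ± 0.34 (-1.50 with adjusted p = 0.812, and -1.07 with adjusted p = 0.311), the T cell attracting chemokine Cxcl9 1.23 ± 1.46 against 4.66 ± 0.37 and its relative Cxcl10 0.69 ± 1.08 against 2.98 ± 0.14. Of 17 T and NK cell genes 6 fell (7 over the list alone), among them the granule proteases Gzma by 3.92 and Gzmb by 1.90 (on slide 3, beside the primary tumours, -0.73 and -0.51, adjusted p = 0.852 and 0.819). Of 14 macrophage genes 7 fell and 2 rose, with Mrc1, a mannose receptor, at 2.98 ± 0.22 against 4.10 ± 0.09 (-0.06 with slide as a block, adjusted p = 0.994). Matrix genes of fibroblasts were lower as well. Postn measured 0.36 ± 0.28 against 2.81 ± 0.44 and the microfibril gene Mfap5 0.01 ± 0.73 against 2.65 ± 0.27, while 5 of 19 fibroblast and stellate cell genes fell and 1 rose (8 and 2 over the list alone). Skeletal muscle genes fell in 9 of 12, such as troponin Tnnc2 by 5.70 log2 (adjusted p = 3.19e-10). For each of the lower genes named here except Isg15, every metastasis animal lay below every primary tumour animal. Krt8 (2.95 ± 0.28 against 2.69 ± 0.29), Krt18 (1.43 ± 0.21 against 1.42 ± 0.19) and Vim (0.99 ± 0.26 against 0.62 ± 0.06) did not pass (adjusted p = 0.564, 0.97 and 0.232).

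In 4T1-2792 limma found 2708 of 20660 genes past the threshold, 1602 higher and 1106 lower. The arrays lay on 4 slides, and metastases of 2 and 3 weeks shared none with the primary tumours. With slide as a block 19 genes passed (12 higher, 7 lower), of which 12 were among the 2708 with the same sign. Among those shared genes were Apoc1 (6.08, adjusted p = 0.0204), Stab2 (4.16, adjusted p = 0.0111), Adm (4.45, adjusted p = 0.0493), Postn (-3.59, adjusted p = 0.0281) and Mfap5 (-4.49, adjusted p = 0.0219). Others had not passed without the block, such as Cdkn1a (0.46 without and 4.31 with it) and Prg4 (0.05 and 3.69), named after their values were seen. The median change of the 2708 genes in the called direction was 0.686 without the block and 0.606 with it, while the median SE of a gene went from 0.164 to 0.592. On slide 3, where 2 metastasis cores of 10 days lay beside the primary tumours, 479 genes passed. Of the 2708, 77.9% had the same sign there, no more than the 80.0% that noise alone gave against the same primary tumour arrays, while their median change there was 0.319, against 0.173 by noise. With slide as a block 83.5% kept their sign, against 70.5% by noise. With genes chosen on other primary tumour animals than those compared on slide 3, the share was 60.4% to 73.1% over 6 splits. Without animal MFP3L 1678 genes passed. By camera the hepatocyte list (median 2.66, adjusted p = 5.3e-32) and the acute-phase list (1.38, adjusted p = 2.72e-21) passed, with adjusted p = 0.00171 for both with an estimated correlation, and so did both with slide as a block (medians 2.75 and 2.64, adjusted p = 1.87e-17 and 2.08e-18). The hypoxia (0.61, adjusted p = 3.51e-09) and neutrophil lists (0.90, adjusted p = 1.46e-05) had adjusted p = 0.133 and 0.127 with an estimated correlation, and medians of 1.46 and 1.35 with slide as a block (adjusted p = 2.33e-13 and 3.72e-05). The type I interferon list (-1.03, adjusted p = 2.36e-14) and the muscle list (-2.04, adjusted p = 2.98e-12) had adjusted p = 0.05 with an estimated correlation, to 2 digits. With slide as a block their medians were -0.49 (adjusted p = 0.0585) and -2.05 (adjusted p = 0.000369). On slide 3 alone the type I interferon median was -0.27 (adjusted p = 0.0322), and that of the interferon gamma list was 0.03 (adjusted p = 0.853, against -1.04 and adjusted p = 2.86e-12 over all arrays, and adjusted p = 0.0971 with an estimated correlation). Cxcl9 (0.11) and Cxcl10 (0.16) did not lie lower on slide 3. The T and NK cell (-0.44, adjusted p = 6.57e-05), macrophage (-0.58, adjusted p = 0.000705), fibroblast (-0.33, adjusted p = 0.00117) and cholesterol lists (0.50, adjusted p = 2.68e-05) had adjusted p = 0.216, 0.204, 0.211 and 0.142 with an estimated correlation.

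Among 9905 genes measured in both lines, 175 were higher in metastases of both, of 205 in 4T1-2776 and 999 in 4T1-2792, where independent draws would give 20.7. Another 13 were lower in both, of 24 and 728, where 1.76 would be drawn. The log2 changes of the lines correlated at r = 0.655 across genes, which are not independent replicates. The hypoxia list mean was higher by 0.42 log2 in 4T1-2776 and by 0.77 in 4T1-2792, with every metastasis animal above every primary tumour animal. The same held for the neutrophil list (1.10 and 1.24) and for the erythroid list, which marks blood (1.27 and 0.98, camera adjusted p = 2.6e-08 and 0.0278, and adjusted p = 0.0464 and 0.395 with an estimated correlation). The neutrophil and erythroid list means were lower in cores than in distant liver in both lines (-0.81 and -0.88, and -1.26 and -1.06).

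**Figure D1:**
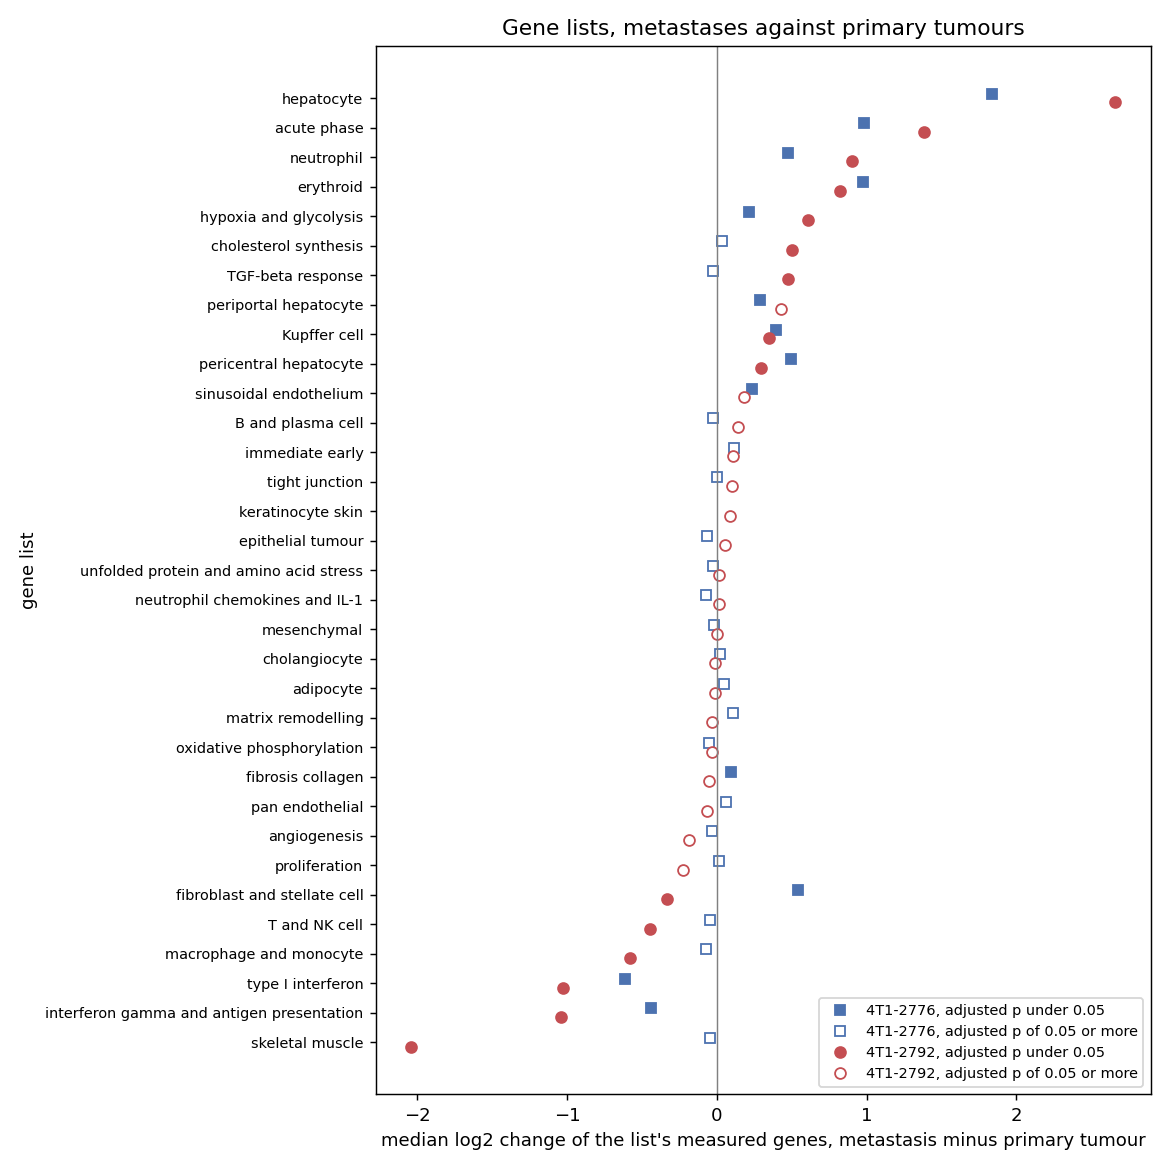
Median log2 change of the measured genes of each list, metastasis minus primary tumour, on the horizontal axis, with 1 line per list; squares are 4T1-2776, circles 4T1-2792, filled where the camera test with the preset correlation passed. The hepatocyte list lies at 1.84 and 2.66 and the type I interferon list at -0.62 and -1.03.

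**Figure D2:**
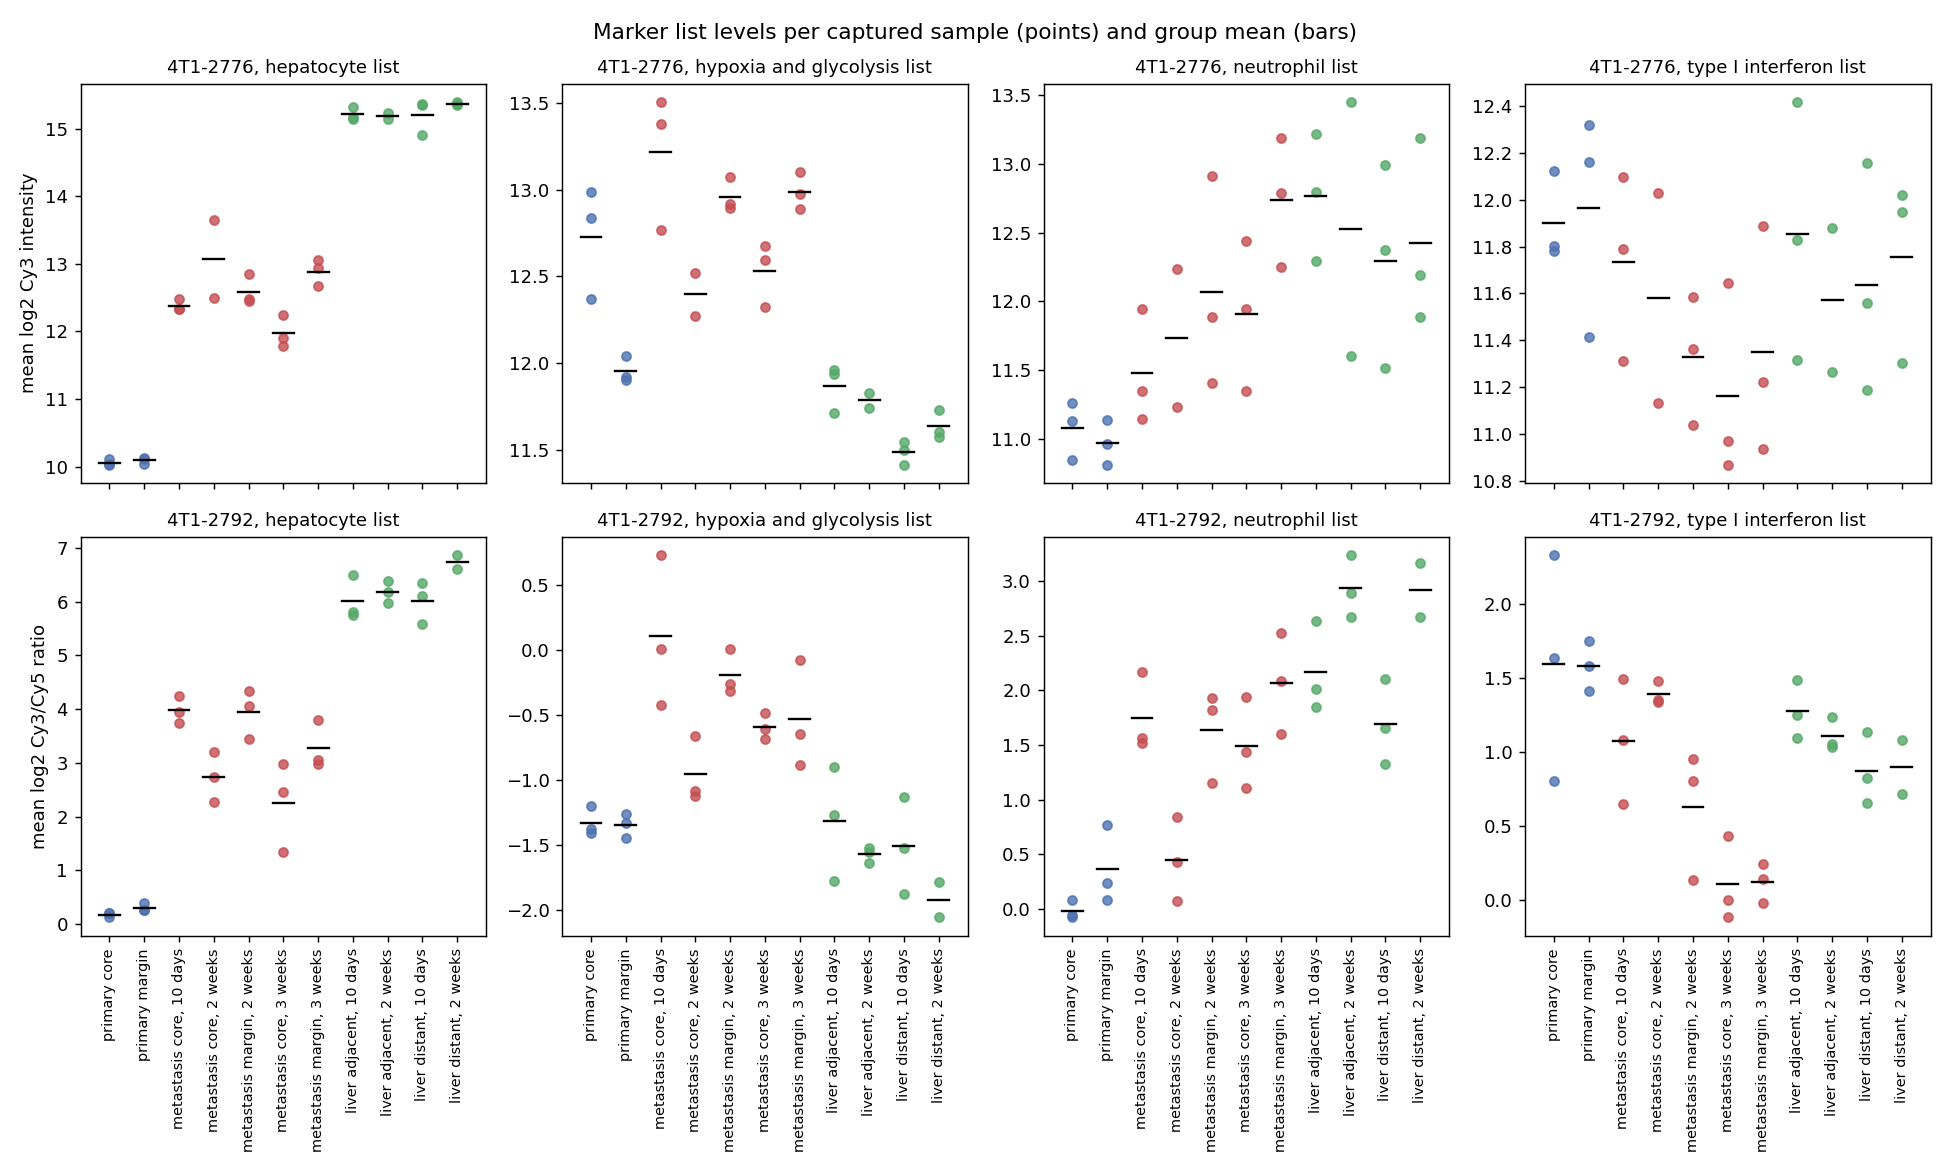
Mean level of 4 marker lists in each sample (points) with group means (bars) over the 11 tissue groups, in log2 Cy3 intensity for 4T1-2776 and in log2 ratio to the reference for 4T1-2792; blue is primary tumour, red metastasis and green liver. Hepatocyte levels of metastases lie between those of primary tumours and of liver in both lines.

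The second comparison asked how the margin of a metastasis, where it meets the liver, differed from its core. In 4T1-2792 liver transcripts were higher at the margin in each animal. Of 20 hepatocyte genes 6 rose (15 over the list alone) and of 24 acute-phase genes 6 rose (14 over the list alone). Alb measured 5.74 ± 0.56 at the margin and 3.95 ± 1.32 in the core (SD, n = 6 each), Fgg 7.16 ± 0.60 against 4.78 ± 1.37, and Igfbp1, a binding protein of insulin-like growth factors, 6.37 ± 1.07 against 3.41 ± 2.20, each higher in 6 of 6 animals. The metal-binding metallothionein Mt2 measured 0.33 ± 0.38 against -1.80 ± 0.83 and Mt1 rose by 1.93 ± 0.31 log2 (SE). Markers of Kupffer cells, the resident macrophages of the liver, rose in 3 of 10 (5 over the list alone). Cd5l (1.91 ± 0.26, adjusted p = 0.000301) and Clec4f (1.56 ± 0.28, adjusted p = 0.00426) were higher in 6 of 6 animals, as was Vsig4, at 2.46 ± 0.38 against 1.16 ± 0.76 (adjusted p = 0.014). Stab2 measured 3.27 ± 0.45 against 1.33 ± 0.38. Of 17 neutrophil genes Camp rose by 2.18 ± 0.48 (adjusted p = 0.0267, 5 of 6 animals), 8 rose over the list alone, and S100a8 measured 4.13 ± 1.11 against 2.45 ± 1.55 (adjusted p = 0.125). The mean of the erythroid list was also higher at the margin in every animal, by 0.59, and by 1.05 in 4T1-2776. Higd1a of the hypoxia list rose by 0.95 (adjusted p = 0.00814, 5 of 6 animals). Lower at the margin in 6 of 6 animals were Cpxm2 (-1.11 ± 0.20, adjusted p = 0.00556) and Mfap5 (-1.23 ± 0.29, adjusted p = 0.0489). Krt18 measured 1.46 ± 0.24 against 1.41 ± 0.19 and Krt8 2.96 ± 0.35 against 2.94 ± 0.41.

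For 4T1-2792 limma found 124 genes past the threshold between margin and core, 117 higher and 7 lower, and quantile scaling gave 382 (221 higher, 161 lower). Core and margin of an animal shared a slide, and the named log2 changes were unaltered with slide as a block. By camera the hepatocyte (median 1.21, adjusted p = 9.07e-23), acute-phase (0.95, adjusted p = 2.85e-17), Kupffer cell (0.44, adjusted p = 1.3e-07) and neutrophil lists (0.77, adjusted p = 1.09e-11) passed, and also with an estimated correlation (adjusted p = 0.00907, 0.00747, 0.00907 and 0.0097). The hypoxia list (0.45, adjusted p = 3.86e-08) had adjusted p = 0.241 with an estimated correlation. At 2 weeks alone 51 genes passed and at 3 weeks alone limma found 0, while the difference between the weeks had 0 genes past the threshold and 704 at an unadjusted p under 0.05. Without 1 animal the count lay between 48 (without animal 6 of 2 weeks) and 114.

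**Figure D3:**
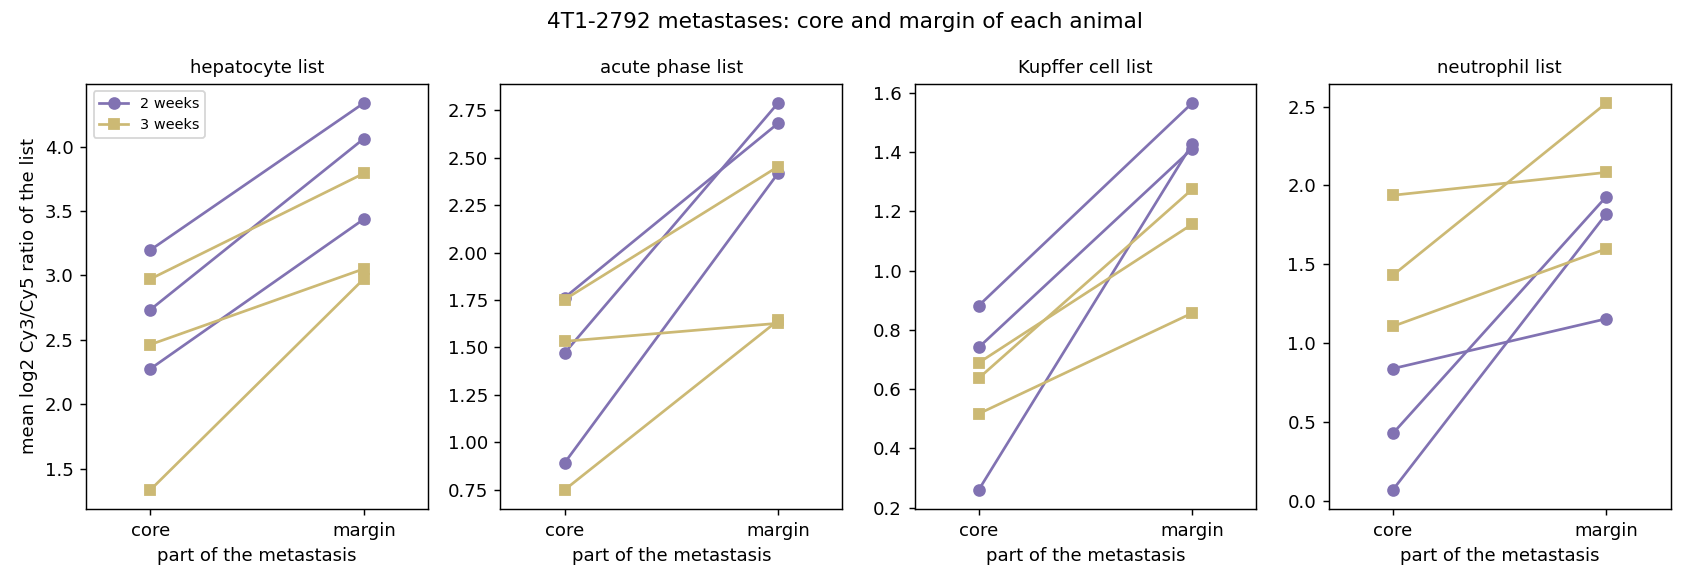
Mean log2 ratio to the reference of the hepatocyte, acute-phase, Kupffer cell and neutrophil lists (vertical axes) in core and margin of 4T1-2792 metastases; each line joins the parts of 1 animal, circles at 2 weeks and squares at 3 weeks. The list medians were higher at the margin by 1.21, 0.95, 0.44 and 0.77 log2.

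In 4T1-2776 no gene passed between metastasis margin and core. Gene groups showed higher means at the margin for hypoxia and glycolysis (18 genes, median 0.42), collagens and fibrosis (15 genes, 0.46) and the acute phase (20 genes, 0.40), of which 5, 2 and 3 passed adjusted over the list alone. Alb measured 14.37 ± 0.62 at the margin (SD, n = 6) and 13.92 ± 1.11 in the core (n = 5), S100a8 13.63 ± 1.67 against 12.31 ± 1.28, higher in 5 of 5 pairs, and Col1a1 13.71 ± 0.87 against 12.02 ± 1.31, higher in 4 of 5 pairs (each adjusted p = 0.734). Krt18 measured 17.39 ± 0.15 against 17.26 ± 0.13. With limma 0 genes passed and 451 had an unadjusted p under 0.05. By camera the hypoxia list had adjusted p = 1.93e-11 (adjusted p = 0.0192 with an estimated correlation), the fibrosis list adjusted p = 5.94e-07 (adjusted p = 0.107 with an estimated correlation) and the acute-phase list adjusted p = 5.21e-06 (adjusted p = 0.216 with an estimated correlation). At 3 weeks alone 15 genes passed, and without animal 4 of 2 weeks or animal 1 of 3 weeks the count was 12 and 9.

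The third comparison set the margin of primary tumours against their core. In 4T1-2776 genes known from fat tissue were among the few higher at the margin. Cfd measured 14.81 ± 0.43 at the margin and 11.42 ± 0.45 in the core (SD, n = 3 each, adjusted p = 6.52e-09), and Plin4, which coats lipid droplets, 12.10 ± 0.18 against 10.88 ± 0.07 (adjusted p = 8.75e-05). Rarres2, which encodes the adipokine chemerin, measured 13.35 ± 0.47 against 11.60 ± 0.42 (adjusted p = 0.000731) and Hp 14.83 ± 0.13 against 11.42 ± 0.51 (adjusted p = 1.03e-10). All were higher in 3 of 3 animals. Of 6 measured adipocyte genes Cfd alone passed, and the list's median was 0.13 (camera adjusted p = 0.0765). Of 18 hypoxia genes none passed over all genes and 6 were lower at the margin adjusted over the list alone, with a median of -0.73. In 4T1-2792 single muscle genes were higher at the margin, though 0 of the 12 genes of the muscle list passed. In the Cy3 channel embryonic myosin Myh3 was at least 16.7-fold higher (15.4-fold by ratios, adjusted p = 3.03e-07), and slow troponin Tnnt1 measured 1.75 ± 1.32 against -1.50 ± 0.12 (adjusted p = 0.00031). Myom2 of the sarcomere rose by 2.45 (adjusted p = 0.00156) and the muscle cofactor Vgll2 was at least 5-fold higher in Cy3 (5.08-fold by ratios, adjusted p = 4.1e-05), each higher in 3 of 3 animals. Lower in 3 of 3 were the neuropeptide precursor Tac1 (0.07 ± 0.54 against 2.06 ± 0.77, adjusted p = 0.000338) and the fibroblast gene Lrrc15 (1.89 ± 0.84 against 3.32 ± 0.45, adjusted p = 0.00779). Krt18 measured 1.47 ± 0.42 against 1.37 ± 0.42 in this line and 17.44 ± 0.10 against 17.42 ± 0.12 in 4T1-2776.

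In primary tumours limma found 5 genes in 4T1-2776, all higher at the margin, of which the fifth is a clone without a gene name, and 30 in 4T1-2792 (23 higher, 7 lower). Array weights gave 12887 genes in 4T1-2776 (7028 higher, 5859 lower), with Krt18 at -0.19 (adjusted p = 0.000832). By camera the muscle list of 4T1-2792 (median 1.56, 0 of 12 genes past over all genes and 6 over the list alone) had adjusted p = 4.52e-07, and adjusted p = 0.863 with an estimated correlation. The hypoxia list of 4T1-2776 had adjusted p = 9.71e-08, and adjusted p = 0.102 with an estimated correlation. Without animal 1034 the 4T1-2776 count was 11, and without animal MFP3L the 4T1-2792 count was 75.

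The fourth comparison asked how liver beside a metastasis differed from liver farther away. In 4T1-2776 annexin Anxa5 measured 13.53 ± 0.48 in adjacent liver (SD, n = 5) and 12.54 ± 0.43 in distant liver (n = 6, adjusted p = 0.0487), higher in 5 of 5 pairs. Krt18 was at 15.95 ± 0.35 against 15.36 ± 0.20 (adjusted p = 0.0869) and Alb at 16.84 ± 0.07 against 16.87 ± 0.24. In 4T1-2792 single genes of mesenchymal and stromal cells were higher beside metastases, 2 of 15 in the mesenchymal list (median 0.01, camera adjusted p = 0.587). The calcium-binding S100a4 measured -2.94 ± 0.81 (n = 6) against -5.32 ± 0.97 (n = 5), the actin-binding Tagln -1.71 ± 0.78 against -4.00 ± 0.45, Vim -2.74 ± 0.38 against -4.12 ± 0.51 and the collagen Col3a1 -0.30 ± 0.31 against -1.66 ± 0.54, each higher in 5 of 5 pairs. S100a4 and Vim were also higher in metastasis cores than in distant liver. Whether tumour cells captured with the adjacent liver carried them was not tested. Smooth muscle actin Acta2 rose by 2.27 ± 0.45 log2 (SE, adjusted p = 0.0238, 4 of 5 pairs). Of 19 fibroblast and stellate cell genes 3 rose and none fell (4 and 2 over the list alone). Among genes lower in metastases than in liver, Rtp3 rose by 0.95 and Tnfrsf11b, a decoy receptor of the TNF family, by 0.96, each in 5 of 5 pairs. Kiss1, which encodes kisspeptin, fell by 0.93 and was lower in 5 of 5 pairs. Krt18 measured 1.14 ± 0.41 against 0.50 ± 0.75 (adjusted p = 0.385).

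Between adjacent and distant liver limma found 2 genes in 4T1-2776 and 51 in 4T1-2792 (44 higher, 7 lower). With slide as a block 15 genes passed in 4T1-2792 and S100a4 (1.51, adjusted p = 0.277), Tagln (1.50, adjusted p = 0.18), Vim (1.07, adjusted p = 0.361), Col3a1 (1.02, adjusted p = 0.402), Acta2 (1.03, adjusted p = 0.745), Rtp3 (1.02, adjusted p = 0.161), Tnfrsf11b (1.03, adjusted p = 0.318) and Kiss1 (-1.01, adjusted p = 0.288) were not among them. With slide as a block the distant liver level of 10 days hung on 1 array, that of animal 10 on slide 2. By camera the TGF-beta response list of 4T1-2776 (12 genes, 1 past and 2 over the list alone, median 0.10) had adjusted p = 8.55e-06, and adjusted p = 0.012 with an estimated correlation. In 4T1-2792 the interferon gamma list (17 genes, 0 past and 4 over the list alone, median 0.38) had adjusted p = 3.77e-05, and 0.66 with adjusted p = 1.19e-07 with slide as a block, but adjusted p = 0.351 with an estimated correlation. The fibroblast list there (median 0.25, adjusted p = 0.0154) had adjusted p = 0.392 with an estimated correlation and a median of 0.12 (adjusted p = 0.305) with slide as a block. Without 1 animal the counts lay between 0 and 11 in 4T1-2776 (0 without animal 3 of 10 days, 11 without animal 1 of 2 weeks) and between 13 and 384 in 4T1-2792 (13 without animal 9 and 384 without animal 6, both of 10 days).

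The fifth comparison followed metastasis cores from 10 days to 3 weeks. In 4T1-2792 lists of liver, interferon and hypoxia genes were lower at 3 weeks with the preset correlation of camera, but not with an estimated one. Of 20 hepatocyte genes 8 fell and none rose (16 over the list alone), with Alb at 3.90 ± 1.91 against 6.68 ± 0.25 (SD, n = 3 each, adjusted p = 0.00401) and the fatty acid carrier Fabp1 at 1.84 ± 1.54 against 6.22 ± 0.72 (adjusted p = 0.000304). Of 17 interferon gamma genes 5 fell (12 over the list alone) and of 18 type I interferon genes 4 fell (11), with Cxcl10 at -0.17 ± 0.43 against 2.74 ± 1.02 and Isg15 at -0.72 ± 0.54 against 0.87 ± 0.25. Of 17 T and NK cell genes 1 fell (6 over the list alone, median -1.05, camera adjusted p = 0.000111, and adjusted p = 0.334 with an estimated correlation). The means of the T and NK cell, sinusoidal endothelium, Kupffer cell and proliferation lists were lower in every animal of 3 weeks than in those of 10 days (-0.98, -0.65, -0.49 and -0.48). Il1b measured 1.01 ± 0.87 against 4.78 ± 0.65 (adjusted p = 3.25e-05). Of 20 hypoxia genes 5 fell (7 over the list alone), such as the glycolytic activator Pfkfb3 by 1.70 and the glucose transporter Slc2a1 by 1.18. Single matrix genes were higher at 3 weeks, while of the 20 genes of the matrix remodelling list 2 rose and 2 fell (median -0.34, camera adjusted p = 0.576). The gelatinase Mmp2 measured 0.30 ± 0.05 against -1.57 ± 0.36 (adjusted p = 1.78e-05), the collagen-degrading protease Ctsk 2.86 ± 0.83 against 0.99 ± 0.04 (adjusted p = 0.00292) and Mfap5 1.46 ± 0.72 against -1.20 ± 0.88 (adjusted p = 0.000553). For each of these genes the animals of the time points did not overlap. In 4T1-2776 the transcription cofactor Eya2 measured 11.60 ± 0.28 at 3 weeks and 13.76 ± 0.12 at 10 days (adjusted p = 0.000175), and the chemokine Cx3cl1 11.73 ± 0.64 against 13.05 ± 0.04 (adjusted p = 0.0126). The circadian gene Noct was higher, at 13.85 ± 0.31 against 11.86 ± 0.69 (adjusted p = 0.0126). Alb measured 13.47 ± 0.54 against 13.29 ± 0.20 and Krt18 17.22 ± 0.12 against 17.55 ± 0.09 (adjusted p = 0.895 and 0.88). Other liver genes were lower at 3 weeks without overlap between animals, though they did not pass. Such were Fabp1 (-2.65, adjusted p = 0.144), Hpx (-1.18, adjusted p = 0.0806) and Ahsg (-1.01, adjusted p = 0.0823), while Apoa1 went the other way (0.49, adjusted p = 0.88).

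Between 10 days and 3 weeks limma found 725 genes in 4T1-2792 (272 higher, 453 lower) and 17 in 4T1-2776 (9 higher, 8 lower). The balance of higher and lower genes in 4T1-2792 depended on the scaling, with 1082 genes by quantile scaling (595 higher, 487 lower) and 10527 in Cy3 alone (9199 higher, 1328 lower). In 4T1-2776 array weights gave 852 (276 higher, 576 lower) and the share of dim genes as a covariate 100 (70 higher, 30 lower). No slide of 4T1-2792 held cores of both times, and with slide as a block 1 gene passed, Mcm3, named after its value was seen. The blocked log2 changes of Alb (-3.03, adjusted p = 0.646), Il1b (-1.88, adjusted p = 0.751) and Mmp2 (0.36, adjusted p = 0.934) did not pass. By camera the hepatocyte list of 4T1-2792 had a median of -1.59 (adjusted p = 5.89e-14, and adjusted p = 0.162 with an estimated correlation), and -1.53 (adjusted p = 0.00138) with slide as a block. The interferon gamma list had -0.97 (adjusted p = 9.37e-10, and adjusted p = 0.223 with an estimated correlation), and -0.87 (adjusted p = 0.000302) with slide as a block. The type I interferon list had -1.04 (adjusted p = 9.39e-09, and adjusted p = 0.223 with an estimated correlation), and -0.55 (adjusted p = 0.175) with slide as a block. The hypoxia list had -0.68 (adjusted p = 6.64e-07, and adjusted p = 0.304 with an estimated correlation), and -0.38 (adjusted p = 0.26) with slide as a block. In 4T1-2776 the hypoxia list was lower at 3 weeks (18 genes, 0 past and 4 over the list alone, median -0.63, adjusted p = 2.44e-11, and adjusted p = 0.02 with an estimated correlation). The mean share of genes below log2 10 was 2.1 percentage points higher on the arrays of 3 weeks there. Without 1 animal the counts were 1 to 23 in 4T1-2776 (1 without animal 1 and 3 without animal 5, both of 10 days, and 3 without animal 4 of 3 weeks) and 236 to 702 in 4T1-2792 (236 without animal 3 and 397 without animal 7, both of 3 weeks, and 388 without animal 6 of 10 days).

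A last comparison set metastasis cores against distant liver as a check of the dissection. Tumour and cell cycle genes were higher in cores and liver genes lower in both lines. S100a4 rose by 6.16 ± 0.45 log2 (SE, adjusted p = 2.13e-10) in 4T1-2776 and by 6.19 ± 0.35 (adjusted p = 9.35e-14) in 4T1-2792, Car9 by 5.20 and 6.05, Vim by 5.28 and 4.90, Krt8 by 1.74 and 1.62 and Krt18 by 2.09 (adjusted p = 6.12e-12) and 0.67 (adjusted p = 0.0169), each in 5 of 5 pairs. Proliferation genes rose in 15 of 20 and 22 of 24 with none falling, such as Mcm6 by 4.37 in 4T1-2776 and Ccna2 by 2.79 in 4T1-2792. Hepatocyte genes fell in 20 of 20 in 4T1-2776 and in 18 of 20 in 4T1-2792, where 2 rose. Alb measured 13.81 ± 1.11 in cores (SD, n = 5) and 16.87 ± 0.24 in distant liver (n = 6) of 4T1-2776, and 5.34 ± 1.57 (n = 6) against 8.70 ± 0.32 (n = 5) in 4T1-2792. Kupffer cell genes fell in 6 of 7 and 8 of 10, such as Vsig4 by 2.80 and 3.92, and S100a8 fell by 2.50 in 4T1-2792 (adjusted p = 0.000158), though it was higher in 2 of 5 pairs. By limma 3449 genes passed in 4T1-2776 (1905 higher, 1544 lower) and 6731 in 4T1-2792 (3578 higher, 3153 lower), of which 1278 were higher and 1316 lower in both among the 9905 shared genes (405 and 335 by independent draws). By camera the hepatocyte list had medians of -2.73 and -3.37 (adjusted p = 2.43e-25 and 1.52e-11, and adjusted p = 0.0024 and 0.0423 with an estimated correlation). The proliferation list had 1.08 and 1.85 (adjusted p = 1.02e-08 and 1.52e-11, and adjusted p = 0.0696 and 0.0662 with an estimated correlation).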

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

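The tests of the Cy5 channel, of acute-phase genes in adjacent liver and of T and NK cells, the fit on slide 3 alone, the simulations and splits of shared primary tumour arrays, the slide tests of 5 lists, the test of 1 liver share gene by gene, the choice of genes on cores of 10 days and the differences between time points were chosen only after the results they bear on had been seen.

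Many genes differed between 4T1-2792 metastases and primary tumours, which lay on different slides. The genes lower in metastases were also lower in the Cy3 channel alone, by a median of 1.52 ± 0.04 log2 (bootstrap SE) relative to all genes, whose median moved by 0.847. This argues against the reference channel as their whole cause. The higher genes were higher in Cy3 by 0.308 ± 0.036 relative to all genes, which leaves a part of it open. Before the median of all genes was taken off, the lower genes moved by -0.677 and the higher by 1.15. The contrast between higher and lower genes thus depends on the scaling, while the lower genes fell either way. Slide as the whole cause is argued against for the hepatocyte, acute-phase, hypoxia and muscle lists, but not for the neutrophil list (1.35 ± 0.9 with slide as a block). With slide as a block the medians of those 4 lists were 2.75 ± 0.62, 2.64 ± 0.57, 1.46 ± 0.24 and, in the lower direction, 2.05 ± 0.67. Within slide 3 they were 3.77, 2.42, 1.72 and 1.94. Each ± is a bootstrap SE of a list's median. An error of the links between slides, which the genes of a list share, was not estimated. The verdicts with slide as a block hold only as far as those links are sound. The metastases on slide 3 were cores of 10 days, a time outside this comparison, so its values do not test slide for metastases of 2 and 3 weeks. Over all called genes the median in the called direction was 0.319 ± 0.01 on slide 3 (0.173 by noise alone, and 0.144 to 0.347 where other primary tumour animals had chosen the genes). It was 0.606 ± 0.018 with slide as a block (0.686 ± 0.0095 without it, 0.257 by noise alone). The block took the median SE of a gene from 0.164 to 0.592, and 83.5% of called genes kept their sign. Across all genes the log2 changes with and without the block correlated at r = 0.606. Whether calls ended by the larger SE or by changed values was not tested. For most called genes outside those 4 lists slide and tissue cannot be told apart. Exceptions are the 12 called genes that also passed with slide as a block, each in the same direction. Within slide 3, 327 called genes passed in the same direction. That fit used cores of 10 days and the primary tumour arrays that had chosen the genes, so passing there does not part slide from tissue. The noise drawn held no slide effect, no slide held primary tumours beside metastases of 2 or 3 weeks, and each link between slides rests on 3 arrays of 1 group. Slide 4, which held the metastases of 2 weeks, is linked to the others by distant liver of 10 days. On the other side of that link stands 1 array, the doubtful one of animal 10. For the other called genes a difference between the tissues stays among the open explanations.

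Acute-phase transcripts stood out among the liver transcripts of metastases. In 4T1-2776 they reached a median of 15.1% of their distant liver level and enzymes of hepatocyte zones 8.19%, and in 4T1-2792 12.1% and 7.91%, with a difference above 0 in 6 of 6 animals of each line. An acute-phase response of the liver beside the tumour is argued against by its list medians, which differed between adjacent and distant liver by 0.0527 ± 0.054 and 0.0288 ± 0.071 log2. Compression of bright spots was matched in 4T1-2792, where genes of like brightness differed by 0.39 ± 0.263 (SD, 11 pairs of genes), and stays open in 4T1-2776, with 0.15 ± 0.424 over 4 pairs. The list differences were 0.997 ± 0.281 and 0.692 ± 0.304 log2, and around the levels that 1 share of liver RNA per animal predicts the genes spread by 1.31 ± 0.28 log2 in 4T1-2776 (SD over genes, and 1.06 without Fgb, the farthest above) and by 1.11 ± 0.16 in 4T1-2792, which leaves such a share open in both lines, while a response of tumour cells themselves was not tested.

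Type I interferon genes were lower in metastases than in primary tumours by the preset correlation, with adjusted p = 0.0793 in 4T1-2776 and 0.05 in 4T1-2792 with an estimated one. Dilution by liver tissue is argued against in part by genes at least 4-fold higher in cores than in distant liver. These lay above the type I interferon list's median by 0.66 ± 0.14 log2 in 4T1-2776 and by 0.908 ± 0.12 in 4T1-2792. Chosen on cores of 10 days, which share no array with the metastases compared, they lay above it by 0.661 ± 0.14 and 0.872 ± 0.13. Both choices took genes for high levels in metastasis cores, which favours genes that do not fall there, so dilution is not excluded. With slide as a block the list's median in 4T1-2792 was -0.491 ± 0.16, which could not tell slide from tissue. The T and NK cell list lay above the interferon list's median by 0.571 ± 0.22 and 0.585 ± 0.27 log2. Both lie within the spread of the 0.5 log2 that would speak against fewer such cells. The T and NK cell list's own median was -0.0442 in 4T1-2776 and -0.443 in 4T1-2792. Fewer T and NK cells may thus contribute in 4T1-2792, while in 4T1-2776 their list's median hardly fell. A difference in interferon signalling between the sites stays open.

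In 4T1-2792 the difference between adjacent and distant liver itself differed between 10 days and 2 weeks for 4 genes by limma, named after their values were seen. Csf1 went from -1.04 to 1.37 log2 (adjusted p = 0.012 for the difference) and Zfp41 from -0.56 to 2.16, while Adrb1 went from 0.81 to -0.84 and Hsd17b7 from 0.69 to -1.08 (each adjusted p = 0.0175). Slide was not in that fit, and with slide as a block 112 genes passed, among them Csf1 (2.35), Zfp41 (3.42) and Adrb1 (-2.12) but not Hsd17b7 (-1.51, adjusted p = 0.178). In the blocked fit 1 array, animal 10 on slide 2, sets the distant liver level of 10 days. On it 24.7% of probes stood well above background in Cy3, the lowest share of all arrays. The blocked fit therefore does not settle whether slide had a part. Between margin and core of primary tumours the mean of the neutrophil list was lower at the margin in every 4T1-2776 animal (-0.107) and higher in every 4T1-2792 animal (0.38). The periportal hepatocyte list moved likewise, with -0.098 and 0.238. These differences between the lines were not tested, and they were found among 33 lists and 6 comparisons, with 3 animals each.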

How the results depend on the processing

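The slide random block, the fit on slide 3, the deposited table for 4T1-2792, the fit without 1 doubtful array and the covariate for dim genes were chosen after seeing the data. In what follows the comparisons are called by metastasis minus primary tumour, margin minus core (of metastases), primary margin minus core, adjacent minus distant liver, 3 weeks minus 10 days and core minus distant liver, and counts are of genes past an adjusted p of 0.05 by limma. Of 3726 values of named genes under alternatives 3138 kept direction and call, 558 lost the call, 15 gained it and 15 reversed. When 1 animal was left out, 1596 of 1818 kept both, 219 lost the call and 3 gained it. The cause was not tested unless given. In 4T1-2792, 24.7% to 44.6% of probes per array stood well above background in Cy3, and 139 of the 2708 genes of metastasis minus primary tumour did so on no array compared.

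Without the animal block the counts moved by more than 1.5 times only for 4T1-2776 margin minus core, from 0 to 1, with 238 and 2762 genes in metastasis minus primary tumour of 4T1-2776 and 4T1-2792. Median-centred arrays, the mean of all probes and the filter on dim genes kept every count they were run on within 1.5 times. Array medians already lay between 11.27 and 11.29 in 4T1-2776 and between -0.0076 and 0.0037 in the ratios of 4T1-2792. Centring could therefore change little. Robust eBayes gave 1 gene for 4T1-2776 adjacent minus distant liver and 11 for 3 weeks minus 10 days. A further 2-fold minimum, fewer genes by construction, left 138 and 781 genes in metastasis minus primary tumour of 4T1-2776 and 4T1-2792, 1821 and 3354 in core minus distant liver, and in 4T1-2792 28 in adjacent minus distant liver and 480 in 3 weeks minus 10 days.

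With array weights 4T1-2776 counts rose to 1427 (metastasis minus primary tumour, 830 higher and 597 lower), 15 (margin minus core), 12887 (primary margin minus core), 293 (adjacent minus distant liver) and 852 (3 weeks minus 10 days), and Krt18 in primary margin minus core turned to -0.19 (adjusted p = 0.000832). The covariate for dim genes gave 743 genes in metastasis minus primary tumour (338 higher, 405 lower), 2 in margin minus core, 8 in adjacent minus distant liver and 100 in 3 weeks minus 10 days. The hepatocyte covariate, which takes up the tissue difference by construction, left 16 genes in 4T1-2776 metastasis minus primary tumour and 2 in 4T1-2792, and turned Stab2 (-0.84), Bnip3 (-0.50) and Dcn (-0.97) in 4T1-2776. Metastasis cores against primary tumour cores, with fewer samples, gave 123 and 941 genes, with Car9 at -0.11 and Bnip3 at -0.25 in 4T1-2776. Metastasis margins against primary tumour margins gave 1392 in 4T1-2792. By time, margin minus core had 15 genes at 3 weeks in 4T1-2776, and 51 at 2 weeks and 0 at 3 weeks in 4T1-2792. Adjacent minus distant liver had 1 gene at 10 days and 0 at 2 weeks in 4T1-2776, and 33 and 25 in 4T1-2792.

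For 4T1-2792, Cy3 alone moved the median of all genes in metastasis minus primary tumour by 0.847 log2 and gave 14023 genes there (11620 higher, 2403 lower), 190 in margin minus core, 5378 in adjacent minus distant liver (511 higher, 4867 lower), 10527 in 3 weeks minus 10 days (9199 higher, 1328 lower) and 11374 in core minus distant liver (3865 higher, 7509 lower). Quantile scaling gave 382 genes in margin minus core (221 higher, 161 lower), 5 in adjacent minus distant liver (all higher) and 1082 in 3 weeks minus 10 days (595 higher, 487 lower). Feature Extraction signals gave 101 in adjacent minus distant liver. The deposited table gave 7482 in metastasis minus primary tumour (3407 higher, 4075 lower), 212 in margin minus core, 16 in primary margin minus core (all higher), 265 in adjacent minus distant liver (175 higher, 90 lower) and 3641 in 3 weeks minus 10 days, with Cd4 at 0.13 there. With slide as a block that table gave 129 (36 higher, 93 lower), 216, 17 (all higher), 1488 and 2 in the same order, with Serpina7 (-0.38) and Rtp3 (-0.13) turned in adjacent minus distant liver and Nlrc5 (0.20) and Slc2a1 (0.61) in 3 weeks minus 10 days.

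Slide as a block in the ratios gave 19 genes in metastasis minus primary tumour, with Ptgis at -0.53, 15 in adjacent minus distant liver (3 higher, 12 lower) and 1 in 3 weeks minus 10 days. Slide as a random block gave 32 in adjacent minus distant liver, and leaving out the distant liver array of 10 days, animal 10, gave 87. Slide 3 alone gave 479 in metastasis minus primary tumour (405 higher, 74 lower), with Cxcl9 at 0.11, Cxcl10 at 0.16 and Il1b at 1.05.

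Leaving out 1 animal gave 174 to 285 genes in 4T1-2776 and 1678 to 2492 in 4T1-2792 for metastasis minus primary tumour (1678 without MFP3L), 0 to 12 and 48 to 114 for margin minus core, 4 to 11 and 20 to 75 for primary margin minus core, 0 to 11 and 13 to 384 for adjacent minus distant liver, 1 to 23 and 236 to 702 for 3 weeks minus 10 days, and 2882 to 3454 and 5577 to 6394 for core minus distant liver. Animals whose omission moved a count by more than 1.5 times were MFP3L for 4T1-2792 metastasis minus primary tumour (1678) and, for 4T1-2776 margin minus core, 1 of 3 weeks (9) and 4 of 2 weeks (12), and for 4T1-2792 10 of 2 weeks (72), 3 of 3 weeks (76) and 6 of 2 weeks (48). For primary margin minus core they were 1034 (11) and MFP3L (75). For 4T1-2776 adjacent minus distant liver they were 1 of 10 days (1), 1 of 2 weeks (11), 3 of 10 days (0), 4 of 2 weeks (4) and 5 of 2 weeks (1), and for 4T1-2792 10 of 2 weeks (33), 3 of 2 weeks (24), 6 of 10 days (384), 6 of 2 weeks (197) and 9 of 10 days (13). For 3 weeks minus 10 days they were 1 of 10 days (1), 4 of 3 weeks (3) and 5 of 10 days (3) in 4T1-2776, and 3 of 3 weeks (236), 6 of 10 days (388) and 7 of 3 weeks (397) in 4T1-2792. Where a group was left with 1 sample, that sample is assumed to vary like the other groups.

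With an estimated correlation the lists past the threshold went from 13 to 8 and from 15 to 2 in metastasis minus primary tumour of 4T1-2776 and 4T1-2792, from 12 to 1 and from 14 to 4 in margin minus core, from 3 to 0 and from 1 to 0 in primary margin minus core, from 10 to 3 and from 14 to 0 in adjacent minus distant liver, from 5 to 1 and from 11 to 0 in 3 weeks minus 10 days, and from 19 to 11 and from 19 to 8 in core minus distant liver. Not run were scaling of both channels between arrays, which leaves ratios as they are, each line fitted on its own, which was the main choice, the mean of probes and the filter on dim genes for 4T1-2776, and every contrast between the lines.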

Other observations

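The relation of other splits to the share of dim genes was examined only after the split counts had been seen.

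Metabolic and vascular gene groups also parted metastasis cores from distant liver. Cholesterol synthesis genes were lower in cores, 7 of 11 in 4T1-2776 (median -1.99 log2, camera adjusted p = 2.47e-08, and adjusted p = 0.0024 with an estimated correlation) and 16 of 18 in 4T1-2792 (-1.19, adjusted p = 2.68e-10, and adjusted p = 0.0189 with an estimated correlation), with none higher. Hmgcs1, which makes the precursor of mevalonate, fell by 2.09 ± 0.19 log2 (SE) and 2.96 ± 0.23, lower in 5 of 5 pairs of each. Oxidative phosphorylation genes fell in 9 of 20 and 18 of 20 (medians -0.60 and -0.87, adjusted p = 1.4e-06 and 1.41e-08, and adjusted p = 0.0936 and 0.106 with an estimated correlation). Angiogenesis genes were higher in 6 of 14 and 9 of 16, with 1 lower in 4T1-2792 (medians 0.55 and 0.94, adjusted p = 0.0202 and 0.00236, and adjusted p = 0.162 and 0.124 with an estimated correlation). Tight junction genes were lower in 3 of 10 and 7 of 16, with 1 higher in 4T1-2792 (medians -0.18 and -0.30, adjusted p = 0.00897 and 0.0225, and adjusted p = 0.0239 and 0.121 with an estimated correlation). Clec4g, a lectin of sinusoidal endothelium, fell by 2.96 ± 0.24 and 4.41 ± 0.36, lower in 5 of 5 pairs of each line. The lines were not tested against each other.

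The labels of 1 sample of 4T1-2776 liver at 2 weeks, animal 5, named it both adjacent and distant, so it entered no comparison. Its hepatocyte list stood at 15.26 log2 Cy3 units, between adjacent (15.15 to 15.24) and distant liver of 2 weeks (15.35 to 15.40), and its proliferation list at 10.76. Its matrix remodelling list stood at 11.47, against 11.45 to 11.51 in adjacent liver of 2 weeks and 11.06 to 11.36 in distant liver of 2 weeks. Its TGF-beta response list stood at 11.36, against 11.30 to 11.38 and 10.91 to 11.05. Its hypoxia list stood at 11.81, against 11.74 to 11.83 and 11.57 to 11.73. Its periportal hepatocyte list stood at 13.45, against 13.08 to 13.20 and 13.40 to 13.89, within distant liver. Its neutrophil chemokine list stood at 11.38, against 11.26 to 11.27 and 11.22 to 11.42, where the ranges overlap and do not part the groups. The lists given here thus leaned to adjacent liver, but the periportal list did not.

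Other splits of the same samples were fitted alone, on genes without missing values, so their real counts can differ from those over all arrays. For metastasis minus primary tumour the arrays of an animal were averaged first and fitted without a block. For metastasis minus primary tumour 1 of 84 splits of the 9 animals, the real one, gave as many genes. Real counts were 200 in 4T1-2776 and 2168 in 4T1-2792, with at most 18 and 4 in other splits, which argues against chance. Chance is also argued against in 4T1-2792 for margin minus core (real 77, 1 of 100 splits, highest other 4) and core minus distant liver (real 6371, 1 of 100, highest other 2980). For core minus distant liver in 4T1-2776 (real 2539, 3 of 100, highest other 7066) other splits gave more genes than the real one. That count alone cannot decide about chance, since the arrays hold a structure that the groups do not explain. Where the real count was 0 each of the 100 splits gave as many by construction, so nothing about chance follows for margin minus core in 4T1-2776 (highest other 9701) or for adjacent minus distant liver (highest other 4778 in 4T1-2776 and 4 in 4T1-2792). The 10 splits of 3 against 3 arrays are too few for a share under 0.05 in primary tumour margin minus core (real 0, highest other 3471 in 4T1-2776 and 0 in 4T1-2792) and in 3 weeks minus 10 days (real 0 and highest other 0 in 4T1-2776, real 725 and highest other 0 in 4T1-2792). Among splits that part as many animals' pairs as the real one, the highest other count for core minus distant liver was 1 in 4T1-2776 and 2980 in 4T1-2792, and for margin minus core in 4T1-2792 it was 0.

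Splits of 4T1-2776 that gave 3471 to 9701 genes where the real one gave 0, and 7066 against 2539 in core minus distant liver, point to a structure of the arrays that the groups do not explain. The split with the highest count parted arrays by their share of genes below log2 10, with a mean difference of 4.32 percentage points in metastasis margin minus core (2.3 for the real split), 3.91 in primary tumours (2.78), 4.21 in liver (0.33) and 4.55 in core minus distant liver (0.16). Slides of these arrays are not given in the sources used here. With that share as a covariate 743 genes passed between metastases and primary tumours, 338 higher and 405 lower.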
